A study of Homo sapiens with 18 samples.

How the data were processed

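RNA was measured by poly(A) RNA sequencing in 18 libraries of human prostate cancer cell lines, in 6 groups of 3. LNCaP cells were untreated or had received genistein or baicalein at 10 or 20 µM for 24 h, and PC-3 cells were untreated. The sample labels call the control libraries untreated, while the treatment protocol describes a DMSO vehicle control. Per the labels' protocols, cells grew in RPMI-1640 with serum, RNA was extracted with TRIzol, and NEBNext Ultra RNA libraries were built from poly(A) RNA. That kit does not mark the strand of origin.

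The deposited table holds 1 count per gene and library, in whole numbers that sum to between 10013567 and 18445711 per library. Per the submitters' processing notes, fastp, STAR 2.7.6a, featureCounts 1.6.4 and DESeq2 1.20.0 were used with the human build GRCh38. The notes give no roles or order for these tools. The strand setting, the treatment of reads that map to several places and the annotation release were not given in the sources used here. Counts of genes that overlap, that lie antisense to each other or that have near-identical copies are therefore uncertain. This holds for FOLH1 and its copy FOLH1B, for TRIM49D1 and TRIM49D2, for HSPA1A and HSPA1B, for the UGT2B, metallothionein, protocadherin gamma and histone families, and for the overlapping mitochondrially encoded mRNAs.

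The table lists 63241 genes, of which 20521 have no symbol and 24834 have no count in any library. GENCODE 29 annotation was matched to 58228 of the identifiers, which hold 99.3% of the counts. It gave gene types, transcript lengths and GC content. Coordinates on GRCh38 are those deposited with the counts. The 18 deposited FPKM columns were not used, because their headers name baicalein at 20 µM 6 times and at 10 µM 0 times. The 13 comparisons made by the authors in the same table were not used, because their groups are coded without a key. Each count column was assigned to its sample by the cell line, drug, concentration and replicate number in its header.

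Before libraries were averaged, each pair within a group was compared by a chi-square statistic over genes. The statistic per degree of freedom lay between 13.3 and 110.1, so no pair of libraries agreed within sampling noise. The labels do not say that replicates came from separate cultures. CPM below, counts scaled to library size, were computed from the deposited counts with TMM factors, and are given as mean ± SD over 3 libraries unless stated otherwise. CPM of untreated LNCaP differ slightly between the drug comparisons and the cell line comparison, because the scaling was computed within each fit. Reads were not collapsed by molecular identifiers, so counting intervals and floors cover counting error only. Intervals of log2 fold changes come from the fit and cover the spread between libraries.

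Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts and robust estimation. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05. All 15 LNCaP libraries entered 1 fit for 9 comparisons, with 16985 genes tested, 10 residual degrees of freedom and a common biological coefficient of variation of 0.234. The comparisons were each drug and dose against untreated, 20 against 10 µM of each drug, genistein against baicalein at each dose, and the drug by dose interaction. The interaction is the genistein step from 10 to 20 µM minus the baicalein step. The 6 untreated libraries entered a second fit for PC-3 against LNCaP, with 17259 genes tested, 4 residual degrees of freedom and a coefficient of variation of 0.208. Log2 fold changes are given ± standard error, computed as the size of the unshrunken log2 fold change over the square root of the F statistic. Intervals place that error around the reported fold change, which is shrunken.

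The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule takes 18 genes of interest in advance, among them FOLH1, KLK3 and CDKN1A. Some genes that the rule takes are not reported here. It also takes, in the main comparisons, the 10 largest rises and the 10 largest falls among called protein-coding genes. These needed a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. In the other comparisons it takes 5 and 5, and for each reported list the 4 members with the smallest adjusted p. The main comparisons are both drugs at 20 µM against untreated and against each other, and PC-3 against LNCaP. Where a gene had no count in 1 group, the fold is a bound against a floor of 3 counts over that group. With 1 to 3 counts the ratio is given with its 95% counting interval.

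There were 32 gene lists with 599 entries, all matched by symbol, and 320 list tests over the 10 comparisons. Each list was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated per list and fry were run beside it. Camera was repeated with RLE normalization and with the replicate block. It was not repeated with each library's trend with GC content and transcript length removed. Some genes belong to more than 1 list. Members that failed the filter on low counts were not tested. A member near 0 in the other groups can pass that filter only through the group where it is high, which favours rises in that group among members tested.

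Alternatives were RLE normalization, no filter on low counts, the replicate number as a block, DESeq2 1.42.0, only the compared groups in the fit, and each library left out in turn. Removal of each library's trend with GC content and transcript length, and omission of the 37 mitochondrially encoded genes, were added after the data were seen. Fold changes of the drugs share the untreated libraries, so their correlation was set beside 20 simulations of unchanged groups that shared simulated controls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

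The procedure was tested on simulated counts. For genistein 20 µM against untreated, with 16200 genes, 5 of 67 genes changed 1.5-fold, 30 of 67 changed 2-fold and 59 of 66 changed 4-fold were called. In that simulation 3 of 16000 unchanged genes were called. For PC-3 against LNCaP, with 15517 genes, the calls were 3 of 67, 32 of 67 and 55 of 66 at those sizes and 14 of 15317 unchanged genes. For the genistein comparison, a list of 30 genes raised 2-fold had an adjusted p of 2.38e-61, and 0 of 100 unchanged lists were called. In a further simulation with 16214 genes, the Spearman correlation of fold change with GC content was 0.457 with a trend added and 0.0129 after its removal.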

Results

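The study concerns genistein and baicalein, plant flavonoids that, per its title, were examined as sensitizers of prostate cancer cells to a radioactive ligand of PSMA. PSMA, the prostate-specific membrane antigen, is encoded by FOLH1. LNCaP is an androgen-sensitive line from a lymph node metastasis of prostate cancer that carries PSMA on its surface. PC-3 is an androgen-independent line from a bone metastasis. Transcript counts covered 5 groups of LNCaP, namely untreated, genistein at 10 and 20 µM and baicalein at 10 and 20 µM, and 1 group of untreated PC-3, with 3 libraries each. Total counts per library ran from 10013567 to 18445711. Genistein is an isoflavone and baicalein a flavone, isomers that differ in where the phenyl ring joins the core and in the placement of the hydroxyl groups. PC-3 was analysed untreated only. The labels do not state separate cultures, so p-values measure only the spread between these libraries, which may be technical.

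Mitochondrially encoded genes took 5.09 ± 0.382% of the counts in untreated LNCaP, 6.05 ± 0.483% with genistein 10 µM, 5.54 ± 0.573% with baicalein 10 µM and 5.62 ± 0.613% with genistein 20 µM. Their share was 12.5 ± 1.97% with baicalein 20 µM, where the 3 libraries had 10.5, 14.5 and 12.4%. In PC-3 it was 4.55 ± 0.361%. Against untreated LNCaP, edgeR called 19 genes with genistein 10 µM, 68 with baicalein 10 µM, 2791 with genistein 20 µM and 9708 with baicalein 20 µM.

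**Figure D1:**
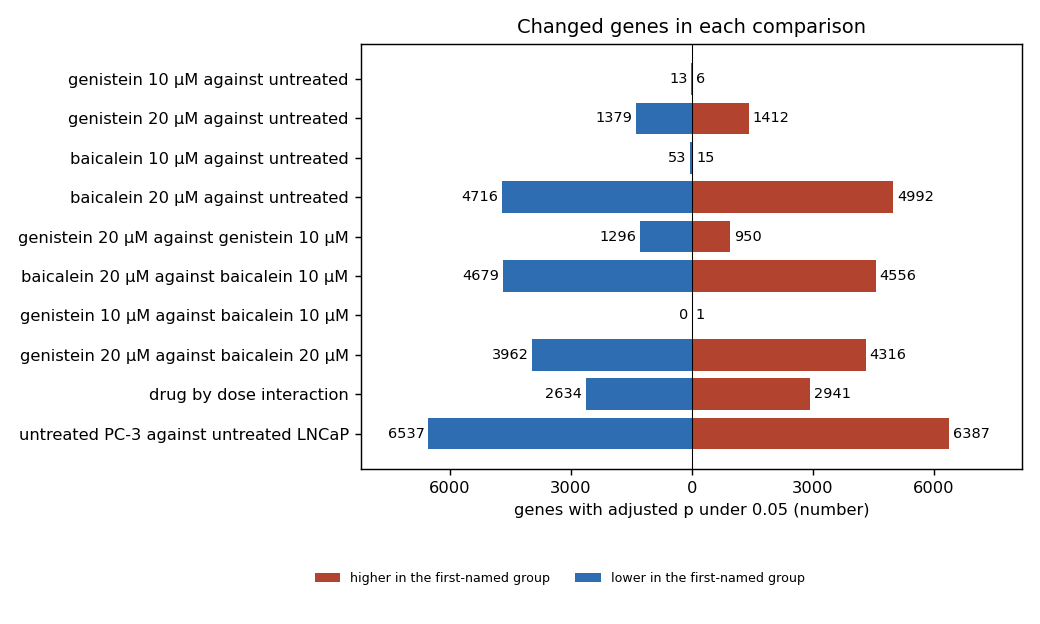
Number of genes called at an adjusted p under 0.05 in each of the 10 comparisons (horizontal axis, genes), with bars to the right for genes higher and to the left for genes lower in the first-named group. Baicalein 20 µM against untreated reached 4992 higher and 4716 lower genes, while the drugs at 10 µM differed in 1 gene.

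The first question was whether the drugs altered the transcript of the radioligand's target. PSMA protein and its level on the cell surface are not measured by these counts. FOLH1 (ENSG00000086205, chromosome 11, 49145092 to 49208638, minus strand, GRCh38) stood at 879 ± 25.6 CPM in untreated LNCaP and at 331 ± 16.7 CPM with baicalein 20 µM. This was a fall of 2.66-fold (log2 fold change -1.41 ± 0.08, adjusted p = 2.52e-08, n = 3 per group, lower in 3 of 3 libraries). FOLH1 was not called with genistein 10 µM (970 ± 27.6 CPM, log2 fold change 0.14, 95% interval -0.03 to 0.32, adjusted p = 0.636). It was not called with genistein 20 µM either (953 ± 33.0 CPM, 0.12, interval -0.06 to 0.29, adjusted p = 0.366). With baicalein 10 µM it stood at 1021 ± 39.1 CPM (0.22, interval 0.04 to 0.39 before adjustment, adjusted p = 0.334). The genistein 20 µM estimate was -0.02 once the GC and length trend was removed. Reads that FOLH1 shares with its near-identical copy FOLH1B could not be told apart by these counts.

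KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), fell 2.04-fold with genistein 20 µM, from 1497 ± 126 to 734 ± 20.3 CPM (adjusted p = 0.00468). With baicalein 20 µM it fell 8.40-fold to 178 ± 62.1 CPM (adjusted p = 1.44e-07). TMPRSS2, a serine protease induced by androgen, fell 2.22-fold with genistein 20 µM, from 324 ± 17.2 to 146 ± 8.48 CPM (log2 fold change -1.15 ± 0.12, adjusted p = 4.91e-05). With baicalein 20 µM TMPRSS2 fell 7.21-fold to 44.9 ± 5.08 CPM (-2.85 ± 0.12, adjusted p = 2.49e-09).

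**Figure D2:**
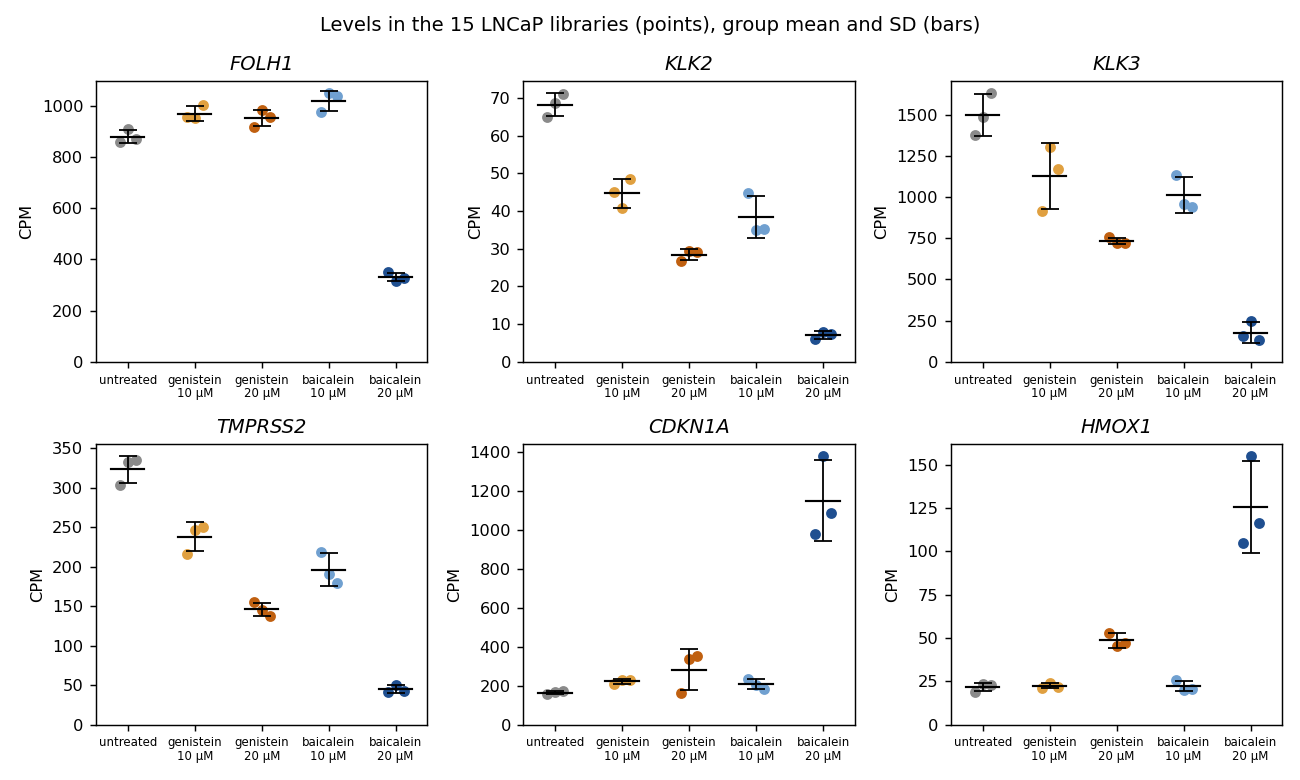
CPM (vertical axes) of FOLH1, KLK2, KLK3, TMPRSS2, CDKN1A and HMOX1 in the 15 LNCaP libraries by treatment, with 1 point per library, a line at the group mean and bars of 1 SD. FOLH1 lay near 331 CPM in the baicalein 20 µM libraries and between 879 and 1021 CPM on average in the other groups.

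With genistein 10 µM 3 immediate early genes rose, and androgen-induced genes lay lower as a list. FOS, a subunit of the AP-1 transcription factor, rose 19.5-fold from 5.82 ± 1.33 to 114 ± 8.88 CPM (log2 fold change 4.28 ± 0.25, adjusted p = 2.69e-06, n = 3 per group). EGR1, an immediate early zinc finger factor, rose 8.39-fold to 12.95 ± 0.915 CPM (3.07 ± 0.16, adjusted p = 1.06e-06), and FOSB rose 16.98-fold (adjusted p = 0.000106). CCN1, a secreted matricellular protein, rose 2.17-fold (adjusted p = 0.00164), TRIB1 1.87-fold (adjusted p = 0.00164) and NDST1, a heparan sulfate modifying enzyme, 2.29-fold (adjusted p = 0.0291). The largest falls were CHRNA2 (3.90-fold, adjusted p = 0.0225), UHRF1 (2.85-fold, adjusted p = 0.0225), ADAM7 (2.33-fold, adjusted p = 0.00857), WWTR1 (2.31-fold, adjusted p = 0.0254) and OTULINL (2.15-fold, adjusted p = 0.00126). FKBP5, an androgen-induced co-chaperone, fell 1.56-fold (adjusted p = 0.0291).

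By lists with genistein 10 µM, 3 of 11 immediate early genes rose and 0 fell (5 and 0 adjusted over the list alone, list adjusted p = 9.97e-13). Of 24 androgen-induced genes 2 fell and 0 rose (15 and 1 adjusted over the list alone, list adjusted p = 3e-16). Mitosis genes lay lower as a list with 0 of 32 members called (2 lower adjusted over the list alone, adjusted p = 1.07e-08), as did homologous recombination and Fanconi genes with 0 of 33 called (4 lower over the list alone, adjusted p = 9.61e-06). At an unadjusted p under 0.05 edgeR found 8 mitosis and 5 recombination genes lower, and DESeq2 called 2 and 1. Examples are CENPF at 13.9 ± 0.361 against 24.5 ± 2.24 CPM (adjusted p = 0.198) and BRCA2 at 4.24 ± 0.993 against 11.3 ± 2.27 CPM (adjusted p = 0.198). DNA replication genes also lay lower, with UHRF1 called among 36 (list adjusted p = 0.000406, adjusted p = 0.109 with an estimated correlation). NRF2 antioxidant targets lay higher with 0 of 18 called, 7 at an unadjusted p under 0.05 and 0 by DESeq2 (adjusted p = 0.00133, adjusted p = 0.0997 with an estimated correlation). Mitochondrially encoded mRNAs lay higher with 0 of 13 called and 1 lower over the list alone (adjusted p = 0.00133, adjusted p = 0.633 with an estimated correlation). There 5 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 1 lower. The list tests were not repeated with the GC and length trend removed, so a part of that trend in these list calls was not tested.

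In all, 6 genes rose and 13 fell of 16985 with genistein 10 µM, against 1458 at an unadjusted p under 0.05 and 129 called by DESeq2. The count was 12 without untreated replicate 3, and 11, 10 and 11 without genistein 10 µM replicates 1, 2 and 3. Calls of FKBP5 and NDST1 ended without any 1 of the 6 libraries (adjusted p 0.0703 to 0.194 and 0.0703 to 0.217). Those of UHRF1 (0.0517 to 0.144) and WWTR1 (0.057 to 0.144) ended without untreated replicate 1 or 3 or any genistein replicate, that of CHRNA2 without untreated replicate 1 or genistein replicate 1 or 2 (0.0894 to 0.178), and that of ADAM7 without genistein replicate 1 or 3 (0.0614 and 0.081). TRIB1 had an adjusted p of 0.0565 with only the compared groups in the fit.

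Baicalein at 10 µM gave a picture close in its named genes. FOS rose 18.6-fold to 108 ± 16.7 CPM (log2 fold change 4.21 ± 0.25, adjusted p = 3.2e-06, n = 3 per group), FOSB 19.3-fold (adjusted p = 6.49e-05) and EGR1 9.32-fold to 14.4 ± 1.18 CPM (adjusted p = 6.18e-07). PPP1R8, a regulator of protein phosphatase, rose 2.21-fold (adjusted p = 0.00309) and CCN1 2.01-fold (adjusted p = 0.00425). GREB1, a hormone-induced growth regulator, fell 2.61-fold from 53.3 ± 1.33 to 20.4 ± 3.25 CPM (-1.39 ± 0.13, adjusted p = 0.000396). Other falls were CHRNA2 (4.57-fold, adjusted p = 0.00695), UHRF1 (3.00-fold, adjusted p = 0.01), ADAM7 (2.39-fold, adjusted p = 0.00514) and WWTR1 (2.34-fold, adjusted p = 0.0125).

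Of 24 androgen-induced genes, 8 fell and 0 rose with baicalein 10 µM (15 and 1 adjusted over the list alone, list adjusted p = 1.04e-16), among them PMEPA1 (1.85-fold), KLK2 (1.78-fold), SLC45A3 (1.84-fold), TMPRSS2 (1.65-fold) and FKBP5 (1.49-fold). Of 11 immediate early genes 4 rose and 0 fell (list adjusted p = 3.69e-10). Of 11 androgen-repressed genes 2 rose, UGT2B15 and UGT2B17, glucuronosyltransferases that inactivate androgens, with near-identical copies (3 over the list alone, adjusted p = 0.000822, adjusted p = 0.142 with an estimated correlation). Both calls ended once the GC and length trend was removed (0.0585 for UGT2B15 and 0.222 for UGT2B17), as did that of the immediate early gene DUSP1 (0.145). DNA replication genes lay lower with 1 of 36 called (4 over the list alone, adjusted p = 5.54e-06, adjusted p = 0.0657 with an estimated correlation). NRF2 targets (0 of 18, adjusted p = 0.000822), hypoxia targets (0 of 22, 1 over the list alone, adjusted p = 0.0133) and heat shock genes (0 of 15, adjusted p = 0.0313) lay higher as lists. With an estimated correlation these had adjusted p = 0.0909, adjusted p = 0.168 and adjusted p = 0.142. At an unadjusted p under 0.05, edgeR found 5, 4 and 3 of their members higher, and DESeq2 called 1 in each. The highest ranked were the quinone reductase NQO1 at 201 against 159 CPM, INSIG2 at 54.5 ± 6.71 against 37.0 CPM and the chaperonin HSPD1 at 1528 ± 76.7 against 1274 ± 62.6 CPM. A part of the GC and length trend in these list calls was not tested either.

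In all, 15 genes rose and 53 fell with baicalein 10 µM, against 1907 at an unadjusted p under 0.05 and 392 called by DESeq2. Without the mitochondrially encoded genes 12 rose and 89 fell. The count was 9 with only the compared groups in the fit, where the genes not called included CCN1 (adjusted p = 0.0617), PMEPA1 (0.0799), CHRNA2 (0.12), KLK2 (0.14), SLC45A3 (0.153), WWTR1 (0.153), ADAM7 (0.161), TMPRSS2 (0.161), DUSP1 (0.166), PPP1R8 (0.175), UGT2B15 (0.187), FKBP5 (0.216) and UGT2B17 (0.218). It was 35, 30 and 32 without untreated replicates 1, 2 and 3, and 22 and 34 without baicalein 10 µM replicates 2 and 3. Calls of FKBP5 (0.0702 to 0.116) and DUSP1 (0.0755 to 0.201) ended without any 1 of the 6 libraries. Baicalein replicate 2 or 3 alone ended those of KLK2 (0.0702 and 0.0599), SLC45A3 (0.0913 and 0.0648) and UHRF1 (0.0702 and 0.0558), and replicate 2 those of PMEPA1 (0.0522), CHRNA2 (0.0609) and WWTR1 (0.0663). The call of TMPRSS2 ended without untreated replicate 2 or 3 or baicalein replicate 2 or 3 (0.0633 to 0.104), that of UGT2B17 without any of these or untreated replicate 1 (0.0574 to 0.145), that of UGT2B15 without untreated replicate 2 (0.0633), and that of WWTR1 also without untreated replicate 1 (0.0587).

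At the matched dose of 10 µM, 1 gene differed between the isomers. NDST1 stood at 105 ± 1.44 CPM with genistein and at 34.4 ± 9.87 CPM with baicalein, 3.04-fold apart (log2 fold change 1.61 ± 0.19, adjusted p = 0.0268, n = 3 per group). FOLH1 differed by -0.07 (95% interval -0.25 to 0.10, adjusted p = 0.752), KLK3 by 0.16 (-0.28 to 0.59, adjusted p = 0.792) and CDKN1A by 0.09 (-0.42 to 0.60, adjusted p = 0.918). The interval of the difference lay within 2-fold for 11572 of 16929 genes, or 68.4%. Mitosis genes lay lower with genistein than with baicalein as a list with 0 of 32 called (adjusted p = 6.45e-06, adjusted p = 0.105 with an estimated correlation). Of these, 10 were lower at an unadjusted p under 0.05 and 0 by DESeq2, with ASPM at 5.05 ± 0.468 against 11.4 ± 4.89 CPM. This list test was not repeated with the GC and length trend removed. Over all genes, 1312 had an unadjusted p under 0.05 and DESeq2 called 70. NDST1 was not called without any genistein 10 µM replicate or without baicalein 10 µM replicate 2 or 3 (adjusted p 0.0781 to 0.162). The count was then 0 without genistein replicate 1 or 3 or baicalein replicate 2 or 3, and 3 without baicalein replicate 1.

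Genistein at 20 µM raised the genes of sterol and fatty acid synthesis. FDPS, farnesyl diphosphate synthase, rose 6.62-fold from 112 ± 8.11 to 743 ± 18.5 CPM (log2 fold change 2.73 ± 0.13, adjusted p = 1.28e-07, n = 3 per group). FDFT1, squalene synthase, rose 5.37-fold from 249 ± 4.93 to 1336 ± 61.8 CPM (2.42 ± 0.11, adjusted p = 1.12e-07), MVD 5.44-fold, MSMO1 9.66-fold, INSIG1 8.20-fold and HMGCS1 11.8-fold. HMGCS1 (4474 ± 2580 against 378 ± 194 CPM, adjusted p = 0.00415) and INSIG1 (adjusted p = 0.00228) are among genes whose counts jumped between libraries of 1 group, so their size is uncertain. Of 22 cholesterol synthesis genes 20 rose and 0 fell (21 and 0 adjusted over the list alone, list adjusted p = 7.07e-23). Of 13 fatty acid synthesis genes 8 rose and 0 fell (9 and 1 over the list alone, adjusted p = 4.32e-07), among them the elongase ELOVL6 (6.45-fold), FADS1 (2.47-fold), ACSS2 (3.83-fold) and SCD (1.99-fold). The call of INSIG2, a sterol-regulated ER protein counted among the hypoxia targets, ended once the GC and length trend was removed (adjusted p = 0.13).

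Outside these lists the largest rises with genistein 20 µM were LURAP1L (18.5-fold, adjusted p = 5.95e-06), GEM (16.0-fold, adjusted p = 0.0016), KRT20 (7.78-fold), ABCB5 (7.46-fold) and GAB2 (6.93-fold). LURAP1L stood at 14.0 ± 2.39 against 0.751 ± 0.159 CPM. The largest falls were SLC6A19, an amino acid transporter (22.2-fold, from 8.29 ± 0.849 to 0.368 ± 0.0576 CPM, adjusted p = 9.22e-06), UVSSA (8.33-fold), ZNF778 (7.64-fold), ZNF737 (7.31-fold), STX16-NPEPL1 (7.11-fold) and ADORA2A (5.36-fold). SPRY4, a feedback inhibitor of MAPK signalling, fell 6.34-fold from 44.9 ± 4.54 to 7.09 ± 1.25 CPM (adjusted p = 2.71e-07), NNMT 4.53-fold, CHRNA2 4.17-fold and YJEFN3 4.11-fold. The call of ZNF737 ended without any 1 of the 6 libraries (adjusted p 0.0544 to 0.101) and that of UVSSA without any genistein replicate (0.0517 to 0.0631). That of ZNF778 (0.0666 to 0.0973) ended without any library except untreated replicate 2, that of STX16-NPEPL1 (0.0513 to 0.17) without any except untreated replicate 3, and that of ADORA2A (0.0559 to 0.164) without any except genistein replicate 1. STX16-NPEPL1 is a readthrough transcript that shares sequence with its parts.

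Of 24 androgen-induced genes 14 fell and 0 rose with genistein 20 µM (18 and 0 adjusted over the list alone, list adjusted p = 1.15e-13). KLK2, a kallikrein protease, fell 2.40-fold, TMPRSS2 2.22-fold, ACP3, prostatic acid phosphatase, 1.98-fold, and FKBP5 1.73-fold. Of 11 androgen-repressed genes 5 rose and 1 fell (adjusted p = 0.0423, adjusted p = 0.258 with an estimated correlation). CAMK2N1 rose 1.74-fold and UGT2B15 1.70-fold, and UGT2B17 rose 1.41-fold, a call that ended once the GC and length trend was removed (adjusted p = 0.123). CYP1A1, a target of the aryl hydrocarbon receptor, fell 6.78-fold from 4.04 ± 1.06 to 0.602 ± 0.242 CPM (adjusted p = 0.000142). The list of these targets was not called. Of its 11 members listed, edgeR tested 5. DESeq2, run without the edgeR filter, called 2 of the listed members higher and 1 lower.

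Several stress lists, though not all, lay higher with genistein 20 µM. Of 25 ATF4 amino acid response genes 12 rose and 0 fell (16 and 1 over the list alone, adjusted p = 4.04e-06, adjusted p = 0.14 with an estimated correlation), with DDIT3 at 218 ± 21.3 against 71.3 ± 3.78 CPM, TRIB3 at 612 ± 34.3 against 220.1 ± 15.4 CPM and CEBPB 2.22-fold higher. Of 18 NRF2 targets 7 rose (10 over the list alone, adjusted p = 2.44e-05), with the haem oxygenase HMOX1 up 2.24-fold to 48.5 ± 4.09 CPM (1.16 ± 0.15, adjusted p = 0.000349), PGD 2.13-fold, ME1 1.90-fold and NQO1 1.31-fold. Of 5 metallothionein genes 4 rose (adjusted p = 7.77e-06), such as MT2A (2.58-fold) and MT1X (2.98-fold), which have near-identical copies. Of 28 p53 targets 4 rose (5 over the list alone, adjusted p = 0.00831), namely BBC3, which encodes the apoptosis protein PUMA (2.59-fold), SESN2 (1.67-fold), XPC (1.39-fold) and the cell cycle inhibitor CDKN1A (282 ± 106 against 164 ± 7.48 CPM, adjusted p = 0.0392). Of 22 hypoxia targets 4 rose (adjusted p = 0.0494, adjusted p = 0.207 with an estimated correlation), namely P4HA2, INSIG2, ALDOC and VEGFA, and this list had adjusted p = 0.0531 under RLE normalization. Of 11 immediate early genes 3 rose (4 over the list alone, adjusted p = 0.00315), with EGR1 at 5.06 ± 0.391 and FOS at 23.6 ± 3.54 CPM. Of 13 mitochondrially encoded mRNAs 5 rose and MT-ND6 fell (10 and 1 over the list alone, adjusted p = 0.00329, adjusted p = 0.468 with an estimated correlation). Heat shock genes (1 of 15 rose, list adjusted p = 0.626) and ER chaperone and unfolded protein response genes (2 of 17 rose, list adjusted p = 0.133) were not called as lists.

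DNA replication and homologous recombination genes lay lower with genistein 20 µM. Of 36 DNA replication genes 15 fell and 0 rose (16 and 0 adjusted over the list alone, list adjusted p = 4.91e-09). UHRF1, which maintains DNA methylation, fell 3.89-fold to 4.41 CPM, E2F8 2.41-fold, the thymidine kinase TK1 1.605-fold and MCM5, a subunit of the replicative helicase, 1.54-fold. Of 33 homologous recombination and Fanconi genes 10 fell and 2 rose (12 and 2 over the list alone, adjusted p = 0.000239), with FANCA down 2.40-fold, FANCI 1.63-fold, XRCC3 1.58-fold and BRCA1 1.58-fold (17.4 ± 1.21 to 11.1 ± 0.961 CPM, adjusted p = 0.00272). The checkpoint kinase ATM was not called (41.9 ± 14.5 against 72.6 ± 12.3 CPM, adjusted p = 0.083). Other repair lists were not called, namely non-homologous end joining (1 of 16 rose, list adjusted p = 0.505), base excision and single-strand break repair (5 of 20 fell and 3 rose, list adjusted p = 0.156) and damage checkpoint genes (4 of 21 fell, list adjusted p = 0.118). Of 32 mitosis genes 4 fell (adjusted p = 0.000581, adjusted p = 0.0628 with an estimated correlation), namely BUB1B, CDC20, PLK1 and MKI67.

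With genistein 20 µM 1412 genes rose and 1379 fell, and without the mitochondrially encoded genes 1076 rose and 1685 fell. The count was 1815, 1661 and 1694 without untreated replicates 1, 2 and 3, and 1679 and 1762 without genistein 20 µM replicates 2 and 3. The calls of CDKN1A (0.1 to 0.153) ended without any untreated replicate or genistein replicate 2 or 3, and that of MKI67 (0.0991 to 0.128) without replicate 2 or 3 of either group. Removal of the GC and length trend also ended the calls of MKI67 (0.102) and PLK1 (0.0935), and a fit of only the compared groups those of CDKN1A (0.107) and PLK1 (0.0582). PLK1 lost its call without untreated replicate 2 or 3 or any genistein replicate (0.0554 to 0.0887), CDC20 without untreated replicate 3 (0.056) or genistein replicate 2 (0.0871), and XPC without any 1 library (0.0556 to 0.118). NQO1 lost it without untreated replicate 2 or 3 or genistein replicate 3 (0.0578 to 0.0916), and VEGFA without untreated replicate 3 (0.0641) or genistein replicate 1 (0.0603). Among the mitochondrially encoded rises, MT-CYB (0.07 to 0.164) and MT-CO2 (0.0536 to 0.0899) lost their call without any library except genistein replicate 3. MT-ND2 lost its call without genistein replicate 1 (0.0774). Removal of the GC and length trend ended those of MT-CYB (0.0954) and MT-ND2 (0.103). The immediate early gene FOSB lost its call without untreated replicate 1 or 3 or genistein replicate 1 (0.0586 to 0.0916).

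Between the genistein doses, the sterol genes were higher and androgen-induced genes lower at 20 µM. FDPS stood at 743 ± 18.5 CPM with 20 µM and at 119 ± 6.06 CPM with 10 µM, 6.25-fold apart (log2 fold change 2.64 ± 0.13, adjusted p = 1.75e-07, n = 3 per group). ELOVL6 was 6.37-fold, MSMO1 11.5-fold, INSIG1 11.7-fold, HMGCS1 11.8-fold, ABCB5 16.0-fold and GEM 17.2-fold higher. SLC6A19 was 28.9-fold, SPRY4 6.17-fold, FOS 4.82-fold, NDST1 4.43-fold and YJEFN3 3.65-fold lower. Cholesterol synthesis (18 of 22 higher, 19 over the list alone, adjusted p = 6.4e-24), fatty acid synthesis (8 of 13 higher and 1 lower, 9 higher over the list alone, adjusted p = 8.29e-07) and metallothionein genes (4 of 5 higher, 5 over the list alone, adjusted p = 8.29e-07) were called. So were the ATF4 list (12 of 25 higher, adjusted p = 8.29e-07, adjusted p = 0.138 with an estimated correlation), NRF2 targets (5 of 18 higher, adjusted p = 0.0388, adjusted p = 0.201 with an estimated correlation) and p53 targets (2 higher and 1 lower of 28, adjusted p = 0.0052). The 2 higher were BBC3 and SESN2, and the lower was BTG2. Androgen-induced genes (7 of 24 lower, 10 lower and 2 higher over the list alone, adjusted p = 0.000765), replication genes (8 of 36 lower, 11 over the list alone, adjusted p = 2.51e-05) and immediate early genes (4 of 11 lower, 5 over the list alone, adjusted p = 0.00692) were lower at 20 µM.

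In that comparison of doses 950 genes were higher and 1296 lower at 20 µM. The count was 1265 and 1224 without genistein 10 µM replicates 2 and 3, and 1256 and 1201 without genistein 20 µM replicates 2 and 3.

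Baicalein at 20 µM changed 57.2% of the genes tested, in libraries where mitochondrially encoded genes held 12.5 ± 1.97% of the counts. Rises and falls are relative to the scaled library, since no absolute reference entered the scaling. TMM normalization takes most genes as unchanged, so the balance of rises and falls rests on that assumption. EGR1 rose 131-fold from 1.54 ± 0.359 to 203 ± 22.6 CPM (log2 fold change 7.04 ± 0.17, adjusted p = 4.13e-11, n = 3 per group). HSPA6, a strictly inducible heat shock protein, rose 135-fold from 2.52 ± 0.303 to 339.9 ± 60.3 CPM (7.07 ± 0.22, adjusted p = 1.53e-10). The chemokine gene CXCL8 rose 157-fold to 19.2 ± 1.90 CPM, GEM 249.7-fold to 87.0 ± 57.1 CPM, HMX3 165-fold to 16.97 ± 2.14 CPM and LURAP1L 104-fold to 79.2 ± 12.8 CPM. NWD2, without a count in the untreated libraries, was at least 94.4-fold higher against a floor of 3 counts over the group (adjusted p = 3.04e-06). With 1 to 3 untreated counts, the ratio was 354 for TNFRSF9 (95% counting interval 97.5 to 2936), 363 for TNF (64.4 to 14390.0) and 159 for ARHGAP25 (43.4 to 1322).

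The largest falls with baicalein 20 µM were SPRY4 (59.1-fold, from 44.9 ± 4.54 to 0.753 ± 0.0845 CPM, adjusted p = 1.53e-10), STUM (51.4-fold), CHRNA2 (39.6-fold), SLC6A19 (36.7-fold), the oestrogen-binding receptor GPER1 (34.9-fold), KCNN2, a calcium-activated potassium channel (25.6-fold, from 197 ± 3.16 to 7.71 ± 2.48 CPM), and PCDHB8 (24.4-fold). PCDHGA3 (28.7-fold) and TRIM49D2 (24.9-fold) also fell and have near-identical or overlapping relatives. C13orf46 had 2 counts over the baicalein libraries, a fall by a ratio of 89.1 (95% counting interval 24.4 to 738.8).

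Of 24 androgen-induced genes 20 fell and 0 rose with baicalein 20 µM (20 and 1 adjusted over the list alone, list adjusted p = 1.41e-10). SLC45A3, a prostate transporter, fell 18.7-fold from 214 ± 9.38 to 11.4 ± 2.02 CPM, KLK2 9.61-fold, ACP3 8.66-fold, TMPRSS2 7.21-fold and FKBP5 4.07-fold (adjusted p = 1.23e-08). Of 11 androgen-repressed genes 8 fell and 2 rose (9 and 2 over the list alone, adjusted p = 0.00294, adjusted p = 0.132 with an estimated correlation). Those that fell include FOLH1, UGT2B17 (4.91-fold) and UGT2B15 (4.57-fold), so androgen-induced and androgen-repressed genes lay lower together. The mitochondrially encoded share of these libraries was 12.5% against 5.09% in untreated cells.

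Cell cycle and recombination genes fell with baicalein 20 µM. Of 32 mitosis genes 28 fell and 0 rose (29 and 0 adjusted over the list alone, list adjusted p = 1.83e-09), with the proliferation marker MKI67 down 6.77-fold from 26.4 ± 3.52 to 3.91 ± 1.28 CPM, BUB1B 9.61-fold, KIF20A 8.56-fold, TPX2 6.38-fold and CDC20 4.74-fold. Of 36 replication genes 28 fell and 1 rose (30 and 1 over the list alone, adjusted p = 1.83e-09), with UHRF1 down 13.5-fold, MCM2 5.57-fold, RRM1, a ribonucleotide reductase subunit, 3.90-fold and MCM5 3.64-fold. Of 33 homologous recombination and Fanconi genes 22 fell and 3 rose (adjusted p = 5.77e-05). FANCA fell 4.89-fold, FANCI 4.55-fold, XRCC3 3.92-fold and BRCA1 3.01-fold to 5.79 ± 0.204 CPM (adjusted p = 3.11e-07). ATM was not called (46.0 ± 15.8 against 72.6 ± 12.3 CPM, adjusted p = 0.07).

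Several stress and death lists, though not all, lay higher with baicalein 20 µM. Of 28 p53 targets 24 rose and 2 fell (list adjusted p = 6.74e-08, with the same counts adjusted over the list alone). CDKN1A rose 6.99-fold from 164 ± 7.48 to 1148 ± 208 CPM (2.81 ± 0.25, adjusted p = 1.02e-06), BBC3 25.3-fold to 109 ± 19.1 CPM, AEN, a nuclease, 8.91-fold, SESN2 8.26-fold, MDM2, the p53 ubiquitin ligase, 2.86-fold (adjusted p = 0.000385), and GDF15 1.73-fold (adjusted p = 0.00977). Of 21 pro-apoptotic genes 12 rose and 2 fell (adjusted p = 0.0126, adjusted p = 0.0591 with an estimated correlation), with the death receptor TNFRSF10B up 4.43-fold, HRK 5.72-fold and BMF down 2.696-fold. Of 16 NF-kB inflammatory genes listed 9 were tested and 8 rose (adjusted p = 5.77e-05), among them RELB (25.2-fold), TNFAIP3 (13.8-fold) and NFKB2 (6.25-fold). Of 13 immediate early genes listed 11 were tested and 11 rose (adjusted p = 3.77e-06), with FOS 17.7-fold, FOSB 13.6-fold and NR4A1 2.82-fold. Of 15 heat shock genes 9 rose and 3 fell (adjusted p = 0.0187, adjusted p = 0.0695 with an estimated correlation), such as HSPA1B (6.63-fold, which shares reads with HSPA1A), DNAJB1 (5.58-fold), BAG3 (3.70-fold) and HSPH1 (2.25-fold). HMOX1 rose 5.79-fold to 125 ± 26.6 CPM (adjusted p = 5.36e-08).

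Metabolic lists also moved with baicalein 20 µM. Of 22 cholesterol synthesis genes 17 rose and 1 fell (17 and 2 adjusted over the list alone, list adjusted p = 1.06e-05), with MVD up 5.72-fold, MVK 5.01-fold, FDPS 4.67-fold and FDFT1 2.92-fold. All 5 metallothionein genes tested rose (adjusted p = 4.59e-05), such as MT1X (9.48-fold) and MT2A (5.68-fold, to 1147 ± 164 CPM). Of 13 mitochondrially encoded mRNAs 12 rose and 1 fell (adjusted p = 4.02e-07, adjusted p = 0.255 with an estimated correlation), beside the 12.5% share of these genes in the counts. MT-ND2 rose 4.55-fold, MT-CO2 3.32-fold and MT-ATP8 2.63-fold, and MT-ATP6, which overlaps MT-ATP8, 15.3-fold from 489 ± 26.3 to 7470.0 ± 605 CPM. CYP1A1 fell 2.84-fold (adjusted p = 0.000749), and the transferrin receptor gene TFRC was not called (266 ± 62.8 against 458 ± 334 CPM, adjusted p = 0.213).

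The other lists were not called by camera with baicalein 20 µM. Camera sets a list against the other genes, and 57.2% of the genes tested changed here. A list not called may therefore still hold many changed members. Fry called 28 of the 32 lists. At an unadjusted p under 0.05, 11 of 20 base excision genes were lower and 6 higher. Of 21 checkpoint genes 11 were lower and 6 higher. Of 18 NRF2 targets 10 were higher and 3 lower, and of 13 fatty acid synthesis genes 8 lower and 4 higher. By camera, adjusted p was 0.593 for oestrogen-induced genes, 0.853 for aryl hydrocarbon receptor targets, 0.126 for NRF2 targets, 0.837 for non-homologous end joining, 0.126 for base excision repair, 0.303 for checkpoint genes and 0.804 for anti-apoptotic genes. It was 0.154 for the ATF4 list, 0.423 for ER chaperones, 0.894 for hypoxia targets, 0.225 for fatty acid synthesis, 0.836 for iron handling, 0.804 for interferon-stimulated genes, 0.261 for MAPK output genes and 0.261 for ribosome biogenesis. It was 0.804 for luminal and for mesenchymal and basal genes, 0.261 for neuroendocrine genes and 0.837 for markers of fibroblasts, endothelium and leukocytes. Median and mean differed in sign for oestrogen-induced genes (0.03 and -0.30) and for the markers of other cell types (-0.40 and 0.23). For luminal genes the median was 0.00 and the mean -0.14, and the test ran against both for aryl hydrocarbon receptor targets (-0.20 and -0.42, test higher) and end joining genes (0.12 and 0.08, test lower). In all, 4992 genes rose and 4716 fell, and no named gene lost its call when 1 library was left out.

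**Figure D3:**
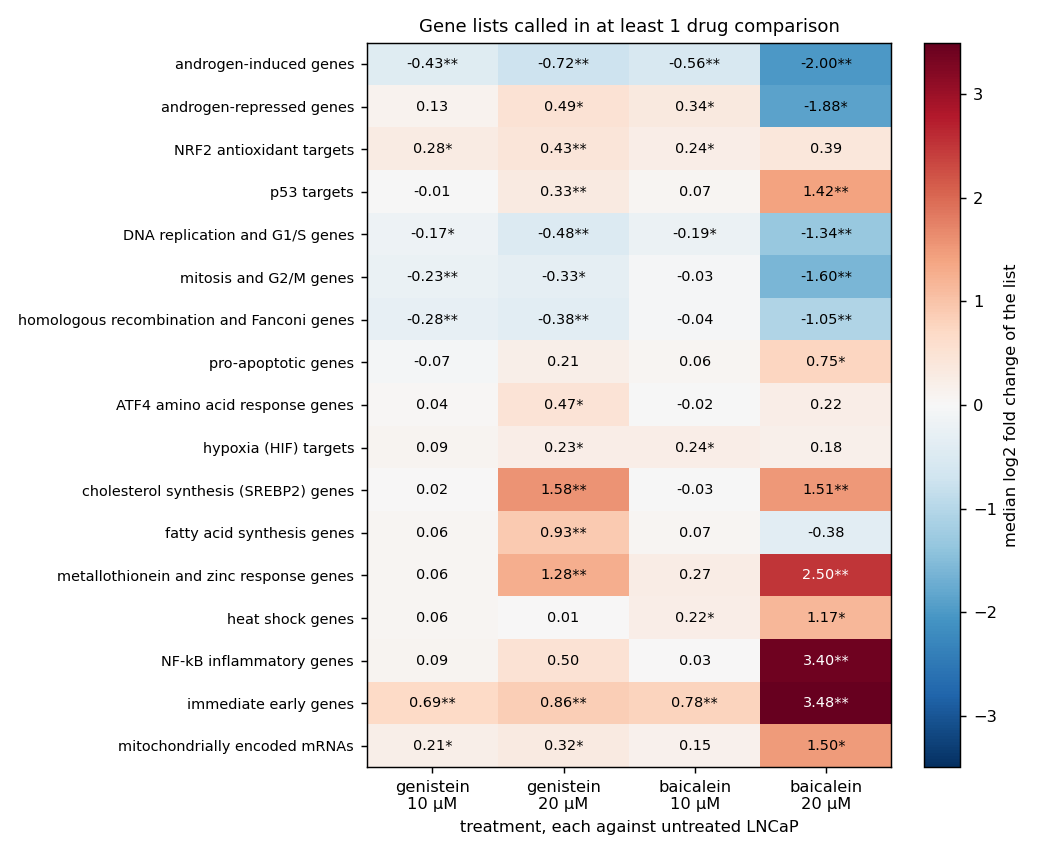
Median log2 fold change (colour and printed value) of the 17 gene lists called in at least 1 of the 4 drug treatments of LNCaP against untreated cells, with 1 star for lists called and 2 stars for lists called also with an estimated correlation. The median of androgen-induced genes was -0.43, -0.72, -0.56 and -1.999 in the order genistein 10 and 20 µM, baicalein 10 and 20 µM.

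Between the baicalein doses, 9235 genes differed. FOLH1 stood at 331 ± 16.7 CPM with 20 µM and at 1021 ± 39.1 CPM with 10 µM, 3.09-fold apart (log2 fold change -1.63 ± 0.08, adjusted p = 1.14e-08, n = 3 per group). SPRY4 was 45.2-fold, STUM 43.4-fold, SLC6A19 34.3-fold, GPER1 30.4-fold and KCNN2 25.3-fold lower. EGR1 was 14.1-fold, GEM 285-fold and BBC3 21.9-fold higher. Without a count at 10 µM, MSANTD3-TMEFF1, a readthrough transcript that overlaps its parts, was at least 370.1-fold and TNF at least 76.9-fold higher. With 1 to 3 counts at 10 µM the ratio was 451 for TNFRSF9 (95% counting interval 80.5 to 17850.0) and 289 for HMX3 (79.5 to 2390.0).

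Lists called between the baicalein doses were androgen-induced (19 lower and 1 higher of 24, adjusted p = 1.65e-08), replication (27 lower and 1 higher of 36, adjusted p = 9.9e-08), mitosis (27 lower and 1 higher of 32, adjusted p = 5.8e-09) and recombination genes (21 lower and 2 higher of 33, adjusted p = 0.000183). Higher at 20 µM were p53 targets (20 higher and 2 lower of 28, adjusted p = 1.2e-07), cholesterol synthesis (16 and 2 of 22, adjusted p = 8.32e-06), metallothionein (5 of 5, adjusted p = 2.96e-05), NF-kB (8 of 9, adjusted p = 3.67e-05) and immediate early genes (9 of 11, adjusted p = 0.00165). Adjusted over the list alone, 28 replication genes were lower and 3 recombination genes higher, and the other counts were as given. Androgen-repressed genes (8 lower and 2 higher of 11, adjusted p = 0.00101), pro-apoptotic genes (11 higher and 3 lower of 21, adjusted p = 0.0138) and mitochondrially encoded mRNAs (12 of 13 higher, adjusted p = 7.73e-08) had adjusted p = 0.0973, adjusted p = 0.0648 and adjusted p = 0.209 with an estimated correlation. In all, 4556 genes were higher and 4679 lower at 20 µM.

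At the matched dose of 20 µM the isomers differed in 8278 genes. FOLH1 was 2.88-fold higher with genistein than with baicalein (953 ± 33.0 against 331 ± 16.7 CPM, log2 fold change 1.53, 95% interval 1.35 to 1.70, adjusted p = 3.56e-08, n = 3 per group). KLK3 was 4.12-fold higher (2.04 ± 0.21, adjusted p = 6.21e-06) and TMPRSS2 3.25-fold higher (1.70 ± 0.12, adjusted p = 2.72e-07). TXNIP, a redox regulator, was 11.1-fold higher with genistein (52.0 ± 2.23 against 4.67 ± 0.479 CPM), KCNN2 17.6-fold, the adrenoceptor gene ADRA2A 16.5-fold, RNF43 15.5-fold, CLDN8 10.7-fold, GPER1 10.3-fold and AKAP5 10.1-fold. PCDHGA3 (30.2-fold), TRIM49D2 (14.4-fold) and TRIM49D1 (13.9-fold) were also higher, with reads uncertain among copies. Lower with genistein were HSPA6 (113-fold), EGR1 (39.9-fold, 5.06 ± 0.391 against 203 ± 22.6 CPM), GZMM (33.1-fold), FAM171B (32.0-fold), ARHGAP25 (29.2-fold), CCNT2 (22.3-fold), TNF (19.9-fold), TBX15 (17.3-fold) and SOCS1 (17.2-fold). CCNT2 stood at 154 ± 234 CPM with baicalein and lost its call without baicalein 20 µM replicate 1 (adjusted p = 0.0965).

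By lists at 20 µM, genistein lay above baicalein in androgen-induced (19 of 24 higher, 20 over the list alone, adjusted p = 2.36e-08), mitosis (26 of 32, 28 over the list alone, adjusted p = 1.16e-08), replication (25 of 36 higher and 2 lower, 26 higher over the list alone, adjusted p = 1.86e-06), recombination (16 of 33 higher and 1 lower, adjusted p = 0.0023) and fatty acid synthesis genes (11 of 13, adjusted p = 7.76e-07). ACLY, ATP citrate lyase, was 3.93-fold and SCD 2.59-fold higher with genistein. It lay below baicalein in p53 targets (19 of 28 lower and 2 higher, 20 lower over the list alone, adjusted p = 6.53e-08), metallothionein (5 of 5, adjusted p = 0.000119), NF-kB (8 of 9, adjusted p = 5.02e-06) and immediate early genes (11 of 11, adjusted p = 1.39e-06). BTG2 was 5.58-fold, AEN 6.91-fold and NFKBIA 2.498-fold lower. With an estimated correlation the call was lost for androgen-repressed genes (8 of 11 higher and 1 lower, adjusted p = 0.000163) at adjusted p = 0.0569, pro-apoptotic genes (10 of 21 lower and 2 higher, adjusted p = 0.0169) at adjusted p = 0.0569, and cholesterol synthesis (10 of 22 higher and 1 lower, adjusted p = 0.0144) at adjusted p = 0.0569. It was lost too for heat shock genes (9 of 15 lower and 3 higher, adjusted p = 0.0118) at adjusted p = 0.0558 and mitochondrially encoded mRNAs (12 of 13 lower, adjusted p = 2.85e-08) at adjusted p = 0.165. In all 4316 genes were higher and 3962 lower with genistein.

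Across genes, fold changes of the drugs at 20 µM correlated with r = 0.58 and rho = 0.55 over 16985 genes, which are not independent replicates. Unchanged groups that shared simulated controls, all drawn at the mean levels of the untreated libraries, gave a mean r of 0.47 (0.41 to 0.49) and rho of 0.44. The deposited untreated libraries themselves did not enter these simulations. The covariance was 0.541 against 0.0742 simulated, a difference of 0.467. Both drugs raised 1065 genes, against 415 for independent lists, and lowered 1047, against 382.9, while 142 changed in opposite directions. The numbers for independent lists do not allow for the shared untreated libraries or for genes that are easier to call. At 10 µM r was 0.50 against a simulated 0.47 (0.42 to 0.52) and the covariance 0.12 against 0.073, a difference of 0.0467, but rho was 0.425, below the simulated 0.44 (0.43 to 0.45), and 64.35% of genes had the same sign against 65.95% simulated. Of the few genes called with genistein 10 µM, 5 of 6 rises and 12 of 13 falls were also called with baicalein 10 µM, and 0 changed in opposite directions. The 3 untreated libraries cannot be split into parts of at least 2, and part of the correlation and of the shared calls at either dose may come from these shared controls.

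**Figure D4:**
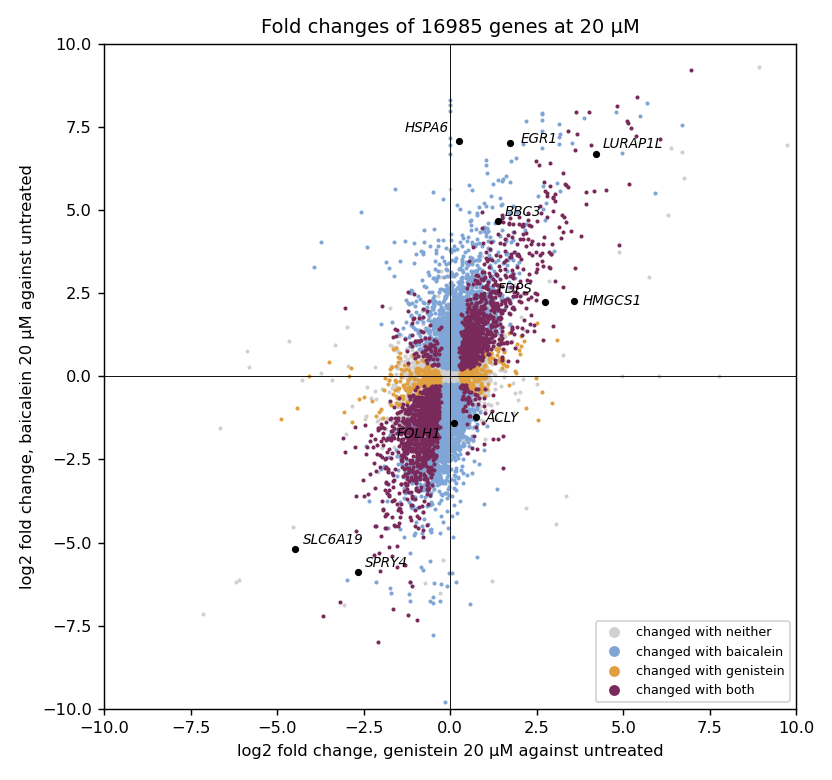
Log2 fold change against untreated LNCaP with genistein 20 µM (horizontal axis) and baicalein 20 µM (vertical axis), 1 point for each of 16985 genes, coloured by the comparisons in which the gene was called. FOLH1 lies at 0.12 and -1.41 and FDPS at 2.73 and 2.22.

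The factorial question was whether the step from 10 to 20 µM differed between the drugs, and it did for 5575 genes, with 2941 more positive and 2634 more negative for genistein. For FOLH1 the genistein step minus the baicalein step was 1.599 ± 0.11 (adjusted p = 1.39e-06) and for KLK2 1.78 ± 0.18 (adjusted p = 1.69e-05). Lists with a higher genistein step were androgen-induced (17 of 24 genes higher, 18 over the list alone, adjusted p = 6.03e-09), androgen-repressed (8 higher and 1 lower of 11, adjusted p = 6.44e-06), mitosis (26 of 32, 28 over the list alone, adjusted p = 6.64e-12), replication (20 of 36, 21 over the list alone, adjusted p = 9.53e-06), recombination (14 higher and 1 lower of 33, adjusted p = 0.000104) and fatty acid synthesis genes (10 of 13, adjusted p = 4.09e-07). Lists with a lower genistein step were p53 targets (14 lower and 2 higher of 28, 17 lower over the list alone, adjusted p = 4.09e-07), metallothionein (5 of 5, adjusted p = 0.000199), NF-kB (6 of 9, adjusted p = 1.6e-05) and immediate early genes (10 of 11, 11 over the list alone, adjusted p = 4.09e-07). Cholesterol synthesis (5 higher and 1 lower of 22, adjusted p = 0.0336), heat shock genes (7 lower and 2 higher of 15, 8 and 3 over the list alone, adjusted p = 0.0239) and mitochondrially encoded mRNAs (12 of 13 lower, adjusted p = 9.9e-10) had adjusted p = 0.0988, adjusted p = 0.0772 and adjusted p = 0.127 with an estimated correlation.

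FOLH1 and most androgen-induced genes tested were lower in PC-3 than in LNCaP. FOLH1 was 664-fold lower in untreated PC-3, at 1.28 ± 0.587 against 855 ± 29.5 CPM (log2 fold change -9.38 ± 0.30, adjusted p = 8.41e-07, n = 3 per group). KLK3 was 914-fold lower (1.604 ± 0.582 against 1456 ± 128 CPM, adjusted p = 4.63e-07), TMPRSS2 4.91-fold and FKBP5 3.33-fold lower. KLK2 had 3 counts over the PC-3 libraries, a ratio of 689 (95% counting interval 235.5 to 3341). Of 26 androgen-induced genes 19 were lower and 4 higher in PC-3 (adjusted p = 0.000167, adjusted p = 0.0634 with an estimated correlation), with PMEPA1 52.97-fold lower. Of 15 luminal epithelial genes 10 were lower and 3 higher, and the list was not called (adjusted p = 0.0662).

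Genes with no or few counts in LNCaP but abundant in PC-3 were among the largest rises. MSMP, a secreted microseminoprotein, stood at 1364 ± 68.0 CPM in PC-3 and was at least 24720.0-fold higher, and the keratin KRT81 at 1262 ± 149 CPM at least 22720.0-fold. S100A10 was at least 11330.0-fold, CXCL6 at least 4937-fold, CXCL1 at least 4098-fold and ANXA3 at least 3485-fold higher. With 1 to 3 counts in LNCaP, the ratio was 40690.0 for the protease PLAU (95% counting interval 7303 to 1607000), 37140.0 for IGFBP4 (6665 to 1467000) and 33050.0 for caveolin, CAV1 (5932 to 1306000). S100A6 was 22820.0-fold higher, and CYP1B1, an oestrogen hydroxylase, at least 109-fold (6.201 ± 4.17 CPM). Without a count in PC-3, HEXA, a lysosomal hexosaminidase, was at least 1029-fold lower, MAGEA10 at least 866.3-fold, ZNF300 at least 540.2-fold, ABCA12 at least 534.4-fold, GLYATL1 at least 513.6-fold and GRK1 at least 472-fold. TRIM49D2 was at least 445.9-fold, ECHDC3 at least 409.2-fold, STAT5B at least 389.4-fold and PCDHB5 at least 388.6-fold lower.

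Of 20 interferon-stimulated genes 20 were higher in PC-3 (adjusted p = 7.05e-07, adjusted p = 0.0639 with an estimated correlation), such as IFIT1 (96.3-fold), IFIT2 (63.6-fold), ISG15 (17.99-fold, 496 ± 72.4 against 27.6 ± 0.753 CPM) and OAS3 (15.5-fold). All 14 NF-kB genes tested, of 16 listed (adjusted p = 3.29e-06), and all 15 MAPK output genes tested (adjusted p = 2.29e-06) were higher. With an estimated correlation each of these lists had adjusted p = 0.0613. Among their members were CXCL8 (611 ± 87.3 against 0.111 ± 0.00966 CPM), ICAM1, LIF, IL1B, DUSP5, PHLDA1, IER3 and EPHA2 (30.1-fold). Of 16 mesenchymal and basal genes 14 were higher and 1 lower (adjusted p = 3.33e-05, adjusted p = 0.0634 with an estimated correlation), with vimentin, VIM, at 1758 ± 144 against 5.995 ± 0.381 CPM and LGALS1 at 2435 ± 326 against 0.219 ± 0.109 CPM. Of 32 mitosis genes 30 were higher and 0 lower (adjusted p = 7.05e-07, adjusted p = 0.0613 with an estimated correlation), with UBE2C 8.73-fold, BIRC5 10.1-fold and MKI67 1.70-fold higher. Of 36 replication genes 29 were higher and 3 lower (adjusted p = 2.31e-05, adjusted p = 0.0898 with an estimated correlation), with TK1 9.33-fold, POLE2 9.62-fold and TYMS 6.83-fold higher. Of 23 hypoxia targets 17 were higher and 3 lower (adjusted p = 0.00319, adjusted p = 0.159 with an estimated correlation), with NDRG1 11.4-fold and PGK1 5.28-fold higher. Of 24 ATF4 genes 16 were lower and 2 higher (adjusted p = 0.00439, adjusted p = 0.367 with an estimated correlation), with PSAT1 5.25-fold and PHGDH 4.18-fold lower and the amino acid transporter SLC7A5 5.92-fold higher. ATM was 2.82-fold, CDKN1A 2.57-fold, MDM2 2.76-fold, GDF15 2.32-fold and CYP1A1 4.27-fold lower, and HMOX1 was not called (adjusted p = 0.0789).

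With an estimated correlation no list was called between the cell lines. Counts adjusted over the list alone equalled those over all genes. In all 6387 genes were higher and 6537 lower of 17259. BRCA1 (1.51-fold lower, adjusted p = 0.0155) lost its call without untreated LNCaP replicate 2 (0.0506) and once the GC and length trend was removed (0.433), and TFRC (2.55-fold higher, adjusted p = 0.036) without untreated LNCaP replicate 2 or 3 or any PC-3 replicate (0.071 to 0.106).

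STAT5B, a signal transducer among the largest falls in PC-3, lies on chromosome 17 (42199176 to 42288633, GRCh38) in a stretch of genes with few or no PC-3 counts. From DHX58 (start 42101404) to ATP6V0A1 (end 42522582) the genes with LNCaP counts included KAT2A (3092 counts over 3 LNCaP libraries against 1 over 3 PC-3 libraries), RAB5C (8312 against 3), STAT3 (8241 against 11) and ATP6V0A1 itself (3844 against 7). These neighbours of STAT5B were chosen after their values were seen. Outside the stretch, NKIRAS2 had 637 counts and NAGLU 328 in PC-3.

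**Figure D5:**
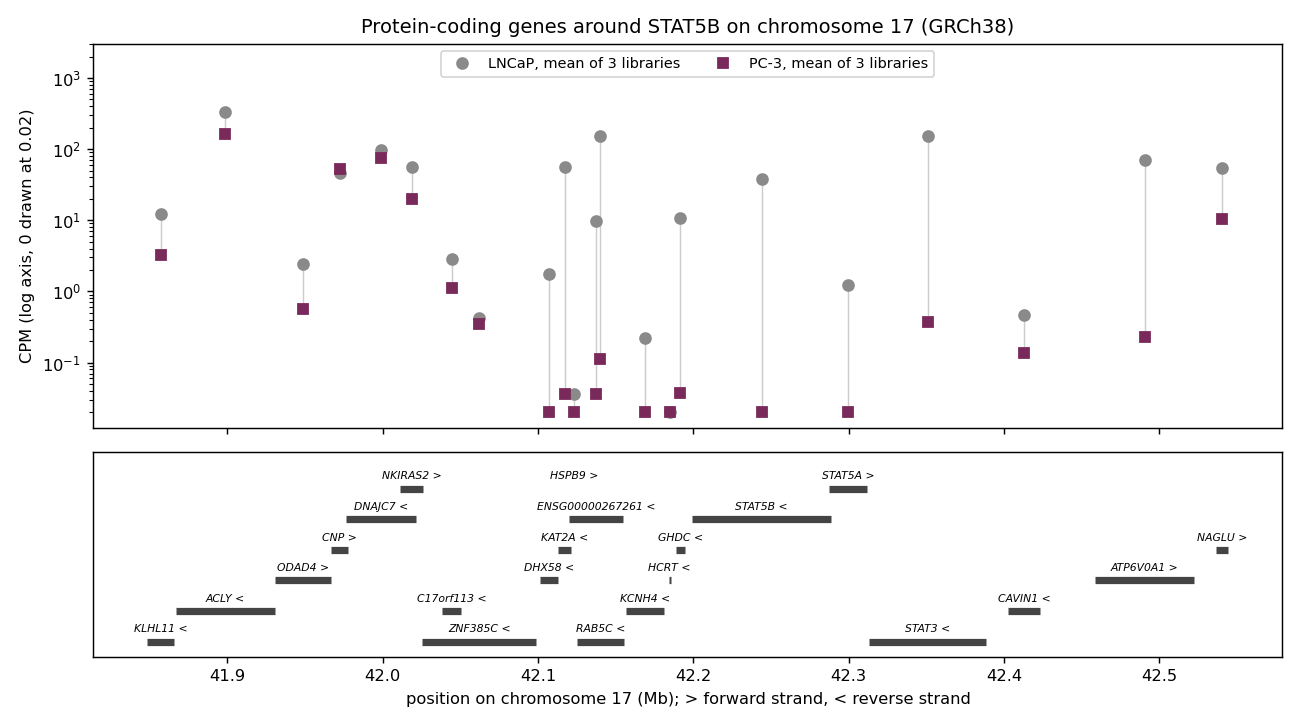
Mean CPM over 3 libraries (log axis, 0 drawn at 0.02) of protein-coding genes around STAT5B in LNCaP and PC-3, above a map of the genes on chromosome 17 in Mb of GRCh38. STAT5B stood at 37.5 CPM in LNCaP and at 0 in PC-3, and NAGLU, beyond the stretch, at 54.6 and 10.5 CPM.

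Over all comparisons 99 of 320 list tests were called, and 59 held with an estimated correlation. Those that held were androgen-induced genes in all 9 LNCaP comparisons except genistein against baicalein at 10 µM, and every other list given above without such a p. In each called list the median, the mean and the test had 1 sign.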

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

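The tests of overlapping genes, of a low level in untreated libraries, of handling and of neighbouring silent genes were chosen only after the results they concern were seen. The step from 10 to 20 µM differed between genistein and baicalein for 5575 genes by the interaction test. Genistein minus baicalein step, on the log2 scale, was 1.599 ± 0.11 for FOLH1 (adjusted p = 1.39e-06) and 1.78 ± 0.18 for KLK2 (1.69e-05). It was 1.886 ± 0.287 for KLK3 (0.000345), 1.425 ± 0.164 for TMPRSS2 (4.39e-05), 1.3 ± 0.145 for FKBP5 (3.6e-05) and 2.04 ± 0.26 for MKI67 (9.32e-05). For BRCA1 it was 0.999 ± 0.171 (0.000782). It was negative for HMOX1 (-1.39 ± 0.22, 0.000426), CDKN1A (-2.115 ± 0.335, 0.000449) and CYP1A1 (-1.69 ± 0.46, 0.0121). FOLH1 moved by -0.03 over the genistein step and by -1.63 over the baicalein step, and CYP1A1 by -2.61 and -0.91. Groups of 3 libraries were not tested for a sample far from the others.

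Other splits of the libraries were counted for each comparison. For the interaction, 2 of 100 splits gave as many genes, the real one with 5575 and another with 5815. The split with 5815 kept the 3 baicalein 20 µM libraries together, as did one with 4399, which points to the structure these libraries give the samples. A split with 555 genes did not keep them together. The count of splits therefore does not separate an interaction from the difference of these libraries from the rest. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split had 19 genes for genistein 10 µM (highest other 3), 2791 for genistein 20 µM (3), 68 for baicalein 10 µM (1) and 9708 for baicalein 20 µM (1), and 1 of 10 splits gave as many in each. Also at 1 of 10 were 20 against 10 µM of genistein with 2246 (highest other 1) and of baicalein with 9235 (2), the drugs at 20 µM with 8278 (3) and PC-3 against LNCaP with 12924 (0). For the drugs at 10 µM 5 of 10 splits gave as many as the real 1 gene, and the highest other was 3.

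The counts of 668 of 4855 genes with a mean over 50 CPM jumped between libraries of 1 group, with a within-group SD over 0.5 on the log2 scale against a median of 0.163 in the others. CLDN4, a tight junction gene, had 6.33, 147 and 1.15 CPM in the 3 untreated libraries. Reads moving between overlapping genes were argued against as the main cause, since 38.6% of the jumping genes overlap another tested gene (95% interval 34.9 to 42.4), against 42.8% of the other well-expressed genes. After each library's GC and length trend was removed, 311 of the 668 genes still jumped (46.6%, 95% interval 42.7 to 50.4). The others fell to an SD of 0.5 or less. The trend thus went with part of the jumps but not all, and whether it was the main cause for the 668 genes could not be told. Reads shared with paralogs or placed at several sites stay open, as does real variation between cultures, and 11 of these genes were called with genistein 20 µM and 206 with baicalein 20 µM.

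FOS stood at 5.82 ± 1.33 CPM in untreated cells, 114 ± 8.88 with genistein 10 µM, 108 ± 16.7 with baicalein 10 µM, 23.6 ± 3.54 with genistein 20 µM and 103 ± 32.0 with baicalein 20 µM. Between genistein 20 and 10 µM 4 immediate early genes differed, so a low untreated level alone cannot account for every difference between the groups. No untreated library entered that comparison. It therefore cannot tell whether a low level in the untreated libraries gave the rise at 10 µM. The GC content and length trend was argued against as the whole cause by the 3 members called with genistein 10 µM, FOS, FOSB and EGR1, which stayed called once it was removed; with JUNB, called only then, 4 were higher. Handling of the 10 µM dishes cannot be told apart from the drugs, since 0 members differed between the drugs at 10 µM by edgeR, and handling goes with dose. A response to a low dose of either drug stays open and was not tested.

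Genes at or near 0 in PC-3 lay next to each other. Of 10433 protein-coding genes with at least 5 CPM in LNCaP, 251 had at most 10 counts over the PC-3 libraries. They made 13 neighbouring pairs from different families against a mean of 5.62 in shuffled genes (permutation p = 0.0041 over 10000 shuffles of the genes), but the stretch from KAT2A to STAT5B on chromosome 17, which prompted this test, supplied 2 of them. Without its genes there were 11 pairs against a mean of 5.42 and a highest of 16 in shuffled genes (permutation p = 0.0194). Family was read only from the opening letters of the symbol. Interleaved neighbours such as CSAG1, MAGEA12, MAGEA2 and CSAG3 on chromosome X therefore gave pairs counted as different. The p argues against chance placement along the chromosomes for the other silent genes, but related neighbours may supply part of it. It does not test this stretch. A candidate explanation for the stretch is a homozygous loss of the region in PC-3, a hypothesis only, since RNA alone does not show a loss of DNA and silencing of the region stays open.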

How the results depend on the processing

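Removal of the GC and length trend and omission of mitochondrially encoded genes were chosen only after the data were seen. Of 5803 alternative values for 453 results of named genes, 5568 kept their direction and side of the threshold, 232 lost the call (163 of these with 1 library left out) and 3 reversed. RLE normalization and DESeq2 ended no such call, no filter on low counts ended 19, only the compared groups 20, the trend removal 12, omission of mitochondrially encoded genes 1 and the replicate block 17. FOLH1, not called in either comparison, reversed to -0.018 with genistein 20 µM once the trend was removed. Between the genistein doses (-0.026) it was 0.044 without a filter and -0.049 to 0.004 with 1 library left out, the highest without genistein 20 µM replicate 1. Counts with the replicate number as a block were 11 for genistein 10 µM, 29 for baicalein 10 µM and 0 between the drugs at 10 µM. The number did not pair samples, as 7 of 30 same-number pairs correlated over 0.1. In the order of these 3 comparisons, DESeq2 called 129, 392 and 70 genes and the trend removal gave 60, 133 and 2. With only the compared groups baicalein 10 µM had 9 and the drugs at 10 µM differed in 0, where fewer libraries leave fewer degrees of freedom. With 1 library left out the counts were 10 to 16 for genistein 10 µM, 1661 to 1938 for genistein 20 µM, 22 to 58 for baicalein 10 µM, 1201 to 1777 between the genistein doses and 0 to 3 between the drugs at 10 µM. The counts for baicalein 20 µM (8846 to 9659), between its doses, between the drugs at 20 µM, for the interaction and for PC-3 stayed within 1.5 times under each alternative run. Of 99 list calls, 59 were made with an estimated correlation and 187 tests were called by fry. The list tests were not repeated with the GC and length trend removed. The correlation of the drugs at 20 µM was 0.650 over genes changed in either comparison, where unchanged genes are left out, and 0.539 to 0.604 with 1 library left out. For the other changes the cause was not tested. A pseudocount alternative planned for values without counts was not run, because the deposited values are counts.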

Other observations

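Families noticed after the data were seen also moved with baicalein 20 µM, and their tests were chosen after that, over 6 families. Of 38 protocadherin genes, which encode neuronal-type adhesion proteins from clustered promoters, 31 fell and 0 rose (adjusted p = 8.8e-08), with PCDHB5 at 38.4 ± 1.22 CPM untreated and 5.38 ± 0.694 CPM treated. With genistein 20 µM 4 fell and 1 rose (adjusted p = 0.00591). Of 31 replication-dependent histone genes 21 rose and 2 fell (adjusted p = 1.2e-05), with H4C14 at 47.7 and 132 ± 22.2 CPM and H3C10 at 16.4 ± 2.26 and 47.9 ± 3.40 CPM. These mRNAs lack poly(A) tails in the main, and the libraries were built from poly(A) RNA. All 4 CLK splicing kinases rose (adjusted p = 0.00128), with CLK1 at 41.6 ± 1.55 and 460.0 ± 99.1 CPM.

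Of 457 zinc finger genes 187 rose and 60 fell with baicalein 20 µM (adjusted p = 0.000316, adjusted p = 0.0893 with an estimated correlation), with ZNF77 at 9.21 ± 0.763 and 150.0 ± 15.4 CPM. Of 83 cytosolic ribosomal protein genes 47 rose and 5 fell (adjusted p = 5.24e-05, adjusted p = 0.329 with an estimated correlation), and of 51 HSPA and DNAJ chaperones 25 rose and 6 fell (adjusted p = 0.00303). RPS19 stood at 225 ± 4.71 and 436 ± 24.0 CPM. With genistein 20 µM 14 of the 83 ribosomal protein genes rose and 3 fell (adjusted p = 1.01e-07, adjusted p = 0.396 with an estimated correlation). The histone, CLK, zinc finger and chaperone families were not called with genistein 20 µM (adjusted p 0.0622 to 0.895). MT-ATP6 stood apart from the other mitochondrially encoded mRNAs with baicalein 20 µM, at a log2 fold change of 3.93 against a list median of 1.497.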
